A study of Arabidopsis thaliana with 4 samples.

How the data were processed

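Small RNA below 200 nt was purified from aerial tissue of 18-day-old Arabidopsis thaliana plants grown at 22 °C with 16 h light and 8 h dark, and sequenced on an Illumina platform, per the labels' protocols. There were 4 libraries, 1 for each of the genotypes Col-0, ein5-1 ski2-3, rdr6-11 and rdr6-11 ein5-1 ski2-3, and groups were taken from the genotype labels.

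The deposited table gives for each of 33602 Arabidopsis loci the authors' count of reads in each library and the authors' RPKM, reads scaled to locus length and library size, per the file headers. CASAVA 1.8.2, BWA and the TAIR9 genome build are named, without roles, per the submitters' processing notes. Read trimming, the treatment of reads that match several places, the use of strand, and the size range kept are not given in the sources used here. The table has no column for read size or strand, so siRNAs, other small RNAs and fragments of longer RNAs were counted together, and reads from a gene and from an overlapping or antisense gene could not be told apart. Of the loci called in any comparison 5 overlap an annotated miRNA or snoRNA gene, among them TAS1B and AT1G63130.

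Dividing counts by RPKM gave a library total and a whole-number length for each locus. The totals so recovered were 828039, 636873, 887508 and 896983 for Col-0, ein5-1 ski2-3, rdr6-11 and the triple mutant, so the table holds 97.6%, 97.6%, 99.0% and 97.8% of the reads the authors scaled to. The RPKM value is 0.001 where the count is 0. The lengths were identical within the pair Col-0 and ein5-1 ski2-3 and within the pair rdr6-11 and triple mutant, and differed between the pairs at 1447 loci, of which 42 held at least 50 reads over all libraries. RPKM was used for this check and for the recovered totals, and all folds were computed from counts.

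Counts were scaled to each library's table total as RPM (808276, 621515, 878632 and 877589 reads), at which 1 read is worth 1.24, 1.61, 1.14 and 1.14 RPM. A locus was called higher or lower when the fold, with a pseudocount of 1 read, was at least 4 and the higher library held at least 50 reads. No test was made and no p-value is given, since each comparison sets 1 library against 1. A model with additive effects over the 4 libraries would leave 1 residual degree of freedom, which holds the interaction of RDR6 with EIN5 and SKI2, and was not fitted. Printed folds of single loci, classes, miRNA families and summed reads carry no pseudocount. Their intervals are exact conditional binomial (Clopper-Pearson) 95% intervals, and shares have exact Clopper-Pearson 95% intervals. Median folds, median log2 folds and log2 folds of single loci carry the pseudocount of 1 read, unless a value is given without it. PCR copies are not independent molecules, so intervals and limits cover counting error only. A library at 0 reads was set to 3 reads, the limit that a count of 0 allows, and the fold is then given as a lower bound. Loci were matched by locus identifier to the TAIR10.1 annotation for names, biotypes and neighbours, and 32835 matched. The unmatched ones were 279 organelle loci, placed by identifier, and 488 nuclear loci. Builds differ, so no coordinates are given.

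Before the data were examined, the 4 comparisons, the rule of size, 14 gene lists and the rule for named genes were fixed. That rule takes, per comparison, the 12 called protein-coding loci of largest fold in the direction asked about, the 5 of largest fold in the other direction, the 8 called loci of largest change in RPM, and members of the lists. BRI1, miRNA families, and the gene groups and single loci described at the end were named after their values were seen. The lists were TAS loci, PPR genes chosen as siRNA sources, auxin receptors and factors, NLR genes, miRNA targets, nitrogen assimilation, the SMXL family, photosynthesis, housekeeping genes, decay and silencing genes, ethylene signalling, the circadian clock, and flower and root markers. List members with at least 10 reads in any library were counted as measured. A list's median log2 fold was placed among 10000 random lists of the same size matched on mean level in 10 classes, as a description of these libraries. The random lists were drawn from loci of every biotype, so no percentile is separated from differences between biotypes.

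Alternatives changed the scaling (median of ratios over 9239 loci with reads in every library, edgeR TMM, reads at miRNA genes, totals without small RNA and organelle classes), the minimum (20, 100 or none), the fold (2 or 8), the pseudocount (5), the counting interval, and the classes kept. Another 4 alternatives were chosen after the data were seen. Against the main scaling the 4 planned scalings shifted the log2 fold of every locus by -0.19, -0.30, -0.04 and -0.54 for the double mutant over Col-0, and by -0.05, 0.00, 0.78 and 0.12 for the triple over the double mutant, in the order listed. For rdr6-11 over Col-0 the shifts were -0.04, -0.03, 0.20 and -0.02, and for the triple mutant over rdr6-11 -0.19, -0.26, 0.55 and -0.40. The rule was tested on counts simulated with counting noise alone over 33602 loci, with 50 loci raised per fold size. The raised loci had at least 20 expected reads in the lower library. The rates below thus do not cover loci with fewer reads there, losses, or variation between libraries beyond counting. For ein5-1 ski2-3 over Col-0 it called 100% of 16-fold and 8-fold, 46% of 4-fold and 0% of 2-fold changes, and 0% of 447 unchanged loci. The other comparisons, in the order given, had 54%, 40% and 40% of 4-fold changes called, 100% of 8-fold and 16-fold changes, 0% of 2-fold changes, and 0% of 479, 514 and 531 unchanged loci. Software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.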

Results

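Small RNA libraries were compared between 4 Arabidopsis genotypes, each sampled as aerial tissue of 18-day-old plants. Col-0 is the wild type. The ein5-1 ski2-3 line (here the double mutant) carries mutations in EIN5, a cytoplasmic exonuclease that degrades mRNA from the 5′ end, and in SKI2, a helicase that works with the cytoplasmic exosome on the 3′ end. The rdr6-11 line carries a mutation in RDR6, an RNA-dependent RNA polymerase that turns single-stranded transcripts into precursors of small interfering RNAs (siRNAs). The rdr6-11 ein5-1 ski2-3 line (the triple mutant) combines them. Each genotype had 1 library. The table held 808276 reads for Col-0, 621515 for the double mutant, 878632 for rdr6-11 and 877589 for the triple mutant, spread over 33602 loci. Between 413 loci (double mutant) and 614 loci (triple mutant) held at least 50 reads. With 1 library per genotype no difference has a replicate check, and intervals are 95% counting intervals that cover counting error only. A locus is called higher or lower below when its reads scaled to the library total (RPM) differed by at least 4-fold and the higher library held at least 50 reads.

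The mutated genes held too few reads to check the labels. EIN5 (AT1G54490) had 2, 2, 0 and 4 reads in Col-0, the double mutant, rdr6-11 and the triple mutant, SKI2 (AT3G46960) had 4, 2, 3 and 3, and RDR6 (AT3G49500) had 1, 3, 0 and 2. The trans-acting siRNA (TAS) loci, whose siRNAs are made through RDR6, gave an indirect check of the rdr6-11 label. Their share of reads was 7.14% (7.09 to 7.20) in Col-0, 2.499% (2.46 to 2.54) in the double mutant, 0.0126% (0.0104 to 0.0152) in rdr6-11 and 0.0519% (0.0472 to 0.0568) in the triple mutant.

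miRNA genes took the largest share of reads in each library, with 52.3% in Col-0, 53.7% in the double mutant, 45.5% in rdr6-11 and 31.2% in the triple mutant. Protein-coding genes took 9.90% in Col-0 and 18.8% in the double mutant, a 1.90-fold difference (1.88 to 1.91), against 10.1% in rdr6-11 and 16.6% in the triple mutant, a 1.65-fold difference (1.63 to 1.66). Chloroplast loci took 9.57% and 9.81% in Col-0 and the double mutant, but 21.2% and 27.1% in rdr6-11 and the triple mutant. The locus lengths implied by the authors' RPKM values were identical between Col-0 and the double mutant, and between rdr6-11 and the triple mutant, but differed at 445 of 12348 loci with reads in both Col-0 and rdr6-11, and at 6.18% of those shared by the double and triple mutants. The authors thus used 2 sets of locus lengths that coincide with the RDR6 genotype, and any difference in handling between the sets would be mixed with RDR6.

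**Figure D1:**
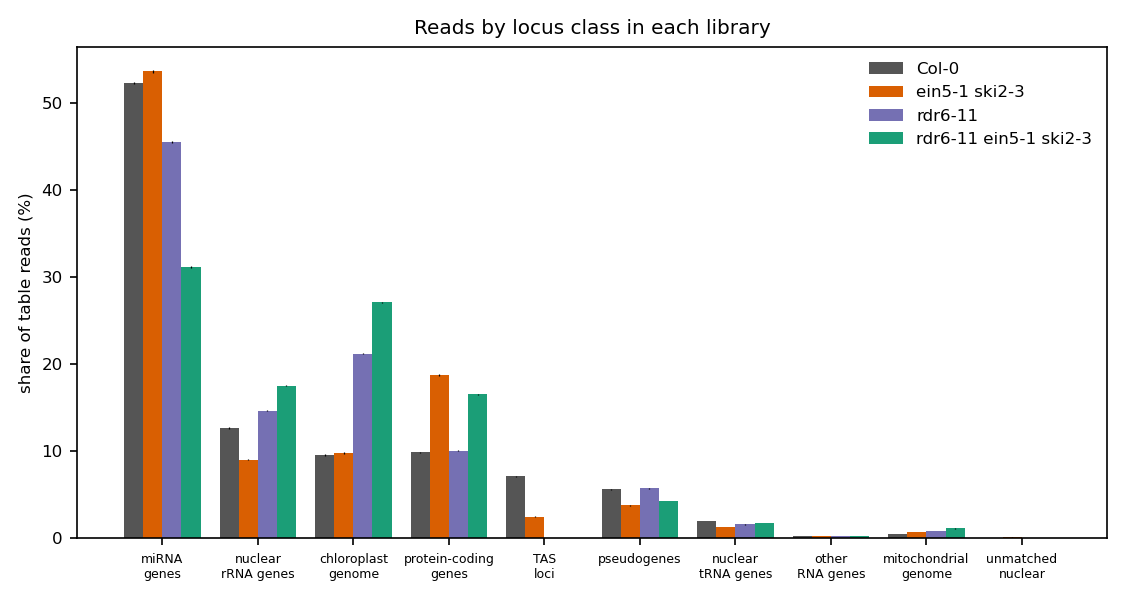
Share of table reads (%) in each class of loci for the 4 libraries, 1 library per genotype, with exact 95% counting intervals as thin lines. The TAS bars reach 7.14% in Col-0 and 2.499% in ein5-1 ski2-3 and are too short to see in the rdr6-11 lines, and the protein-coding bars reach 18.8% in ein5-1 ski2-3 against 9.90% in Col-0.

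The first comparison asked which loci gained small RNA reads when EIN5 and SKI2 were both mutated. The largest fold was at a member of the SMXL family, which includes repressors of strigolactone signalling. SMXL5 (AT5G57130), which acts in phloem formation, held 3 reads in Col-0 and 3617 in the double mutant, a 1568-fold difference (536 to 7607). SMXL4 (AT4G29920) held 1 and 596 reads (775-fold, 139 to 30665), and SMXL7 (AT2G29970) held 3 and 138 (59.8-fold, 20.1 to 294). Also among the largest folds were the auxin response factor ARF6 (AT1G30330, 0 and 491 reads, at least 213-fold), the auxin-conjugating GH3 enzyme DFL1 (AT5G54510, 4 and 1056 reads, 343-fold, 134 to 1262) and NPY5 (AT4G37590, 2 and 1108 reads, 720.5-fold, 199 to 5957). The CYP79B2 (AT4G39950) and CYP79B3 (AT2G22330) enzymes, which convert tryptophan to indole-3-acetaldoxime, were at 0 reads in Col-0 and at 285 and 205 in the double mutant, at least 123.5-fold and 88.9-fold higher.

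By the rule of size 175 loci were higher and 59 lower in the double mutant than in Col-0. Of the 175, 163 were protein-coding, out of 285 protein-coding genes with at least 50 reads in either library. These 163 held 1739 reads in Col-0 and 36803 in the double mutant, so most passed the 50-read minimum only through the double mutant. Their share of the 285 thus follows in part from that minimum. The other loci of largest fold were CRF2 (AT4G23750), a cytokinin response factor, with 0 and 722 reads (at least 313-fold), the flavin monooxygenase FMO (AT1G12200) with 0 and 541 (at least 234.5-fold), the polyamine oxidase PAO5 (AT4G29720) with 0 and 254 (at least 110.1-fold), the glucosyltransferase UGT84A2 (AT3G21560) with 0 and 236 (at least 102-fold) and AT2G39870 with 4 and 1128 (367-fold, 143 to 1348). GAE6 (AT3G23820), a UDP-glucuronate epimerase of pectin synthesis, held 36 and 1984 reads (71.7-fold, 51.6 to 103).

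Among the lists fixed before the data were examined, the 31 measured miRNA target genes held 9 higher and 2 lower members. The higher members included the HD-ZIP III leaf and vascular regulators PHB (AT2G34710, 2 and 279 reads, 181-fold, 49.8 to 1505) and ATHB8 (AT4G32880, 1 and 255, 332-fold, 59.0 to 13149), the Argonaute AGO1 (AT1G48410, 12 and 121, 13.1-fold, 7.24 to 26.1) and the ubiquitin-conjugating enzyme PHO2 (AT2G33770, 31 and 386, 16.2-fold, 11.2 to 24.2), which limits phosphate uptake. The lower members were AGO2 (AT1G31280, 405 and 59 reads, 5.28-fold lower, 4.01 to 7.06) and the AP2-type gene TOE2 (AT5G60120, 163 and 27, 4.64-fold lower, 3.08 to 7.26). The list's median log2 fold was 3.08 (3.38 at the bound, without the pseudocount and with members at 0 set to 3 reads). It lay at percentile 100 of 10000 random lists of matched level, drawn from loci of every biotype. Of loci with at least 50 reads in either library, 163 of 285 protein-coding genes were higher. Only 3 of 90 miRNA genes and 4 of 107 pseudogenes were, and the rank was not separated from that difference. The difference itself follows in part from the minimum, which most of the 163 passed only in the double mutant. Of the 6 measured SMXL genes 3 were higher, with a median log2 fold of 3.88 (4.30 without the pseudocount) at percentile 99.9. Both nitrate reductase genes were higher, NIA1 (AT1G77760) 18.0-fold (9.76 to 36.8) and NIA2 (AT1G37130) 20.2-fold (12.5 to 34.5), out of 6 measured nitrogen assimilation genes. Of the 6 measured members of the auxin receptor list only AFB2 was called, 4.05-fold higher (3.35 to 4.92), and that call was lost under each of the 4 other scalings. In the ethylene list the F-box gene EBF1 (AT2G25490), whose product targets EIN3 for degradation, was 37.5-fold higher (16.9 to 104). The list median was 2.02 (2.25 without the pseudocount) at percentile 96.4, and the other 5 measured members were not called.

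Reads at miRNA genes and TAS loci went the other way at many loci. Of the 59 lower loci 24 were miRNA genes and 14 protein-coding. MIR167d (AT1G31173) was 4.80-fold lower (4.61 to 5.01), MIR158a (AT3G10745) 5.46-fold (5.17 to 5.78), MIR161 (AT1G48267) 4.502-fold (4.16 to 4.88) and MIR172b (AT5G04275) 5.27-fold (4.77 to 5.83). The protein-coding loci lower by the largest fold were DIN10 (AT5G20250), a dark-inducible raffinose synthase family gene (59 and 3 reads, 15.1-fold lower, 4.93 to 75.4), TIM10 (AT2G29530), a mitochondrial import chaperone (10700 and 792 reads, 10.4-fold, 9.66 to 11.2), the histidine biosynthesis gene ATP-PRT1 (AT1G58080, 163 and 14 reads, 8.95-fold, 5.19 to 16.7), AT2G06420 (59 and 7 reads, 6.48-fold, 2.96 to 16.8) and AT3G06435 (4756 and 647 reads, 5.65-fold, 5.21 to 6.15). DIN10, TIM10 and AT3G06435 overlap other annotated genes, and their reads could not be told apart from those of the overlapping genes. The summed reads of the 8 TAS loci were 2.86-fold lower (2.81 to 2.91). The TAS list had a median log2 fold of -1.74 at percentile 0.12, with TAS3B (AT5G49615) lower by the rule of size. TAS4 (AT3G25795), whose siRNAs target MYB genes, was the exception, with 8 reads in Col-0 and 1080 in the double mutant (176-fold, 88.8 to 408). The PPR list, described below, was 1.54-fold lower in sum (1.47 to 1.60), with a median log2 fold of -0.32 at percentile 48.7. Of its 19 measured members 0 were higher and AT5G41170 was lower (4.96-fold, 3.82 to 6.53). Of 12 measured genes of the NLR list 0 were called, with a median of 0.93 at percentile 91.7. The split of 175 higher against 59 lower became 162 against 95 with TMM scaling and 153 against 134 with totals that left out TAS, miRNA, organelle, rRNA and tRNA loci.

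The next comparison asked which of these reads were lower where RDR6 was mutated as well, by setting the triple mutant against the double mutant; the 2 libraries come from different sets. SMXL5 held 3617 reads in the double and 13 in the triple mutant (393-fold lower, 229 to 739), SMXL4 held 596 and 2 (421-fold, 116 to 3483) and DFL1 held 1056 and 7 (213-fold, 103 to 531). FMO held 541 and 0 reads, at least 255-fold lower, and the GH3 enzyme WES1 (AT4G27260) 255 and 0, at least 120.0-fold. The growth regulator GRF5 (AT3G13960) held 640 and 4 (226-fold, 87.8 to 832).

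By the rule of size 105 loci were lower and 98 higher in the triple mutant. The lower loci were 92 protein-coding genes, all 6 TAS loci with at least 50 reads in either library, and 7 others. TAS2 (AT2G39681) was 43.9-fold lower (37.3 to 51.9), TAS1C (AT2G39675) 43.0-fold (36.1 to 51.7), TAS1A (AT2G27400) 84.5-fold (60.8 to 121) and TAS3A (AT3G17185) 27.4-fold (22.4 to 33.7), and TAS4 held 1080 and 0 reads, at least 508-fold lower. The 23 listed genes of the pentatricopeptide repeat (PPR) family, RNA-binding proteins of organelles, were chosen as known sources of secondary siRNAs. They thus serve as a reference for RDR6 and do not stand for the whole family. Reads were lower at 9 of their 19 measured members, with a median log2 fold of -3.09 (-3.10 at the bound) at percentile 0. Those named by fold were AT1G63130 (420 and 0 reads, at least 198-fold), AT1G63080 (250 and 0, at least 118-fold), RPF3 (AT1G62930, 318 and 1, 449-fold, 80.01 to 17790) and AT1G63150 (406 and 2, 287-fold, 78.8 to 2375). Of 12 measured immune receptor genes of the NLR class, AT5G38850 (658 and 5 reads, 186-fold, 79.2 to 574) and AT5G43740 (190 and 4, 67.1-fold, 25.8 to 249) were lower. The auxin receptors AFB2 (AT3G26810, 10.8-fold, 8.23 to 14.5) and AFB3 (AT1G12820, 16.3-fold, 8.81 to 33.5), 8 miRNA targets including ARF6 (86.7-fold, 43.6 to 202) and PHB (21.9-fold, 13.6 to 37.5), the 3 SMXL genes and both nitrate reductase genes (8.59-fold, 5.60 to 13.7, for NIA1 and 5.18-fold, 4.01 to 6.77, for NIA2) were lower as well, NIA2 short of 4-fold when scaled to reads at miRNA genes. The auxin list had a median log2 fold of -1.59 (-1.69 without the pseudocount) at percentile 0.76 over 6 measured members. The NLR list stood at -0.57 (-0.58 at the bound) at percentile 3.85. The miRNA targets stood at -2.37 (-2.82 at the bound), at percentile 0, and the SMXL genes at -2.80 (-2.92 without the pseudocount), at percentile 0.04. The glutamate synthase gene GLU1 was 6.30-fold higher (3.91 to 10.7). AT3G44570 held 140 and 0 reads (at least 65.9-fold), and was also at 0 against 457 in rdr6-11.

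Of the 98 higher loci 59 were protein-coding and 19 chloroplast. LHCA4 (AT3G47470), a light-harvesting protein of photosystem I, held 843 and 13854 reads (11.6-fold, 10.9 to 12.5) and TIM10 held 792 and 8480 (7.58-fold, 7.05 to 8.17). DIN10 held 3 and 140 (33.1-fold, 11.1 to 162), AT3G22210 held 18 and 591 (23.3-fold, 14.6 to 39.5), AT3G06435 held 647 and 3799 (4.16-fold, 3.83 to 4.53) and the Calvin cycle regulator CP12-2 (AT3G62410) held 9 and 253 (19.9-fold, 10.3 to 44.0). In the photosynthesis list 3 of 26 measured members were higher, LHCA4, RCA and GAPB, with a median log2 fold of 1.02 (1.03 at the bound) at percentile 99.2. The housekeeping genes moved as much (1.11, percentile 98.8), and nuclear rRNA genes were 1.94-fold higher (1.92 to 1.96), from 9.04% to 17.55% of reads. The plastid triose phosphate isomerase TIM (AT2G21170, 1 and 267 reads, 189-fold, 33.7 to 7496) and the NLR-type locus AT1G63750 (2 and 77, 27.3-fold, 7.30 to 229) were at 1 or 2 reads in both libraries of the first set and far above in both of the second, and the implied length of AT1G63750 differed between the sets (4511 and 4515). The 98 higher loci became 223, against 81 lower, when libraries were scaled to reads at miRNA genes, and 138 against 99 when organelle loci were left out of the totals, a setting chosen after the data were seen. Most miRNA reads in each library were those of miR159 and miR396, so the scaling to miRNA reads follows these families.

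Both criteria, higher in the double mutant than in Col-0 and lower in the triple than in the double mutant, were met by 77 loci, 70 of them protein-coding. They held 0.108% of reads in Col-0, 4.29% in the double mutant, 0.0896% in rdr6-11 and 0.274% in the triple mutant. Among them were the brassinosteroid receptor BRI1 (AT4G39400) with 10, 978, 16 and 53 reads in the 4 libraries, CRF2 with 0, 722, 0 and 6, and CYP79B2 with 0, 285, 0 and 11. Both ratios share the double mutant library. In 100 simulations of counting noise alone 0 such loci arose, as the rule calls no unchanged locus under that noise, and other variation of the shared library was not simulated. Independent lists would share 33.2, a number that leaves the shared library out of account. Among protein-coding genes alone 70 met both criteria against 56.0 for independent lists, a smaller excess than over all classes. The scaling to reads at miRNA genes gave 55 loci, all among the 77.

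**Figure D2:**
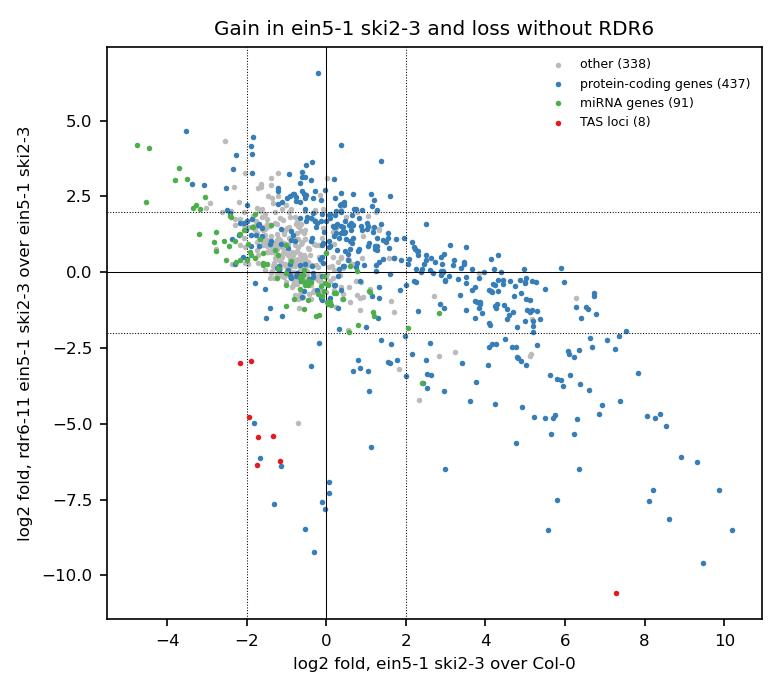
Each point is 1 of 874 loci with at least 50 reads in any library, coloured by class; the x axis is the log2 fold of ein5-1 ski2-3 over Col-0 and the y axis that of rdr6-11 ein5-1 ski2-3 over ein5-1 ski2-3, with a pseudocount of 1 read, and dotted lines mark 4-fold. The lower right corner holds the 77 loci that met both criteria, with TAS4 the lowest, and both axes use the ein5-1 ski2-3 library.

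Without the decay mutations, rdr6-11 was set against Col-0, again across the 2 sets, to find reads lower with RDR6 mutated in otherwise wild-type plants. The reads at TAS loci were 565-fold lower (469 to 687) in sum. TAS2 held 20441 reads in Col-0 and 26 in rdr6-11 (855-fold, 583 to 1309), TAS1C 12886 and 32 (438-fold, 309.9 to 640.2), TAS3A 10056 and 22 (497-fold, 328 to 793), TAS1A 9421 and 19 (539-fold, 345 to 896) and TAS1B (AT1G50055) 4691 and 2 (2550-fold, 705 to 21060). The PPR genes AT1G63130 (682 and 0 reads, at least 247-fold) and AT1G63150 (574 and 0, at least 208-fold) and the NLR gene AT5G38850 (811 and 1, 882-fold, 158 to 34864) were lower too.

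Only 22 loci were lower and 11 higher by the rule of size. All 7 TAS loci with at least 50 reads in either library were among the 22, with 14 protein-coding genes and 1 pseudogene. Of the 19 measured genes of the PPR list, chosen as siRNA sources, 9 were lower. The list's median log2 fold was -3.48 (-2.90 at the bound) at percentile 0. Its lower members included RPF2 (AT1G62670, 104 and 0 reads, at least 37.7-fold), RPF3 (422 and 1, 459-fold, 81.9 to 18161), AT1G63070 (170 and 0, at least 61.6-fold), AT1G63080 (472 and 3, 171-fold, 58.2 to 832) and AT1G62910 (1173 and 205, 6.22-fold, 5.36 to 7.25). AT5G43740 (114 and 0 reads, at least 41.3-fold) was the other NLR gene called. AFB2 was 8.64-fold lower (5.27 to 15.0) and AFB3 28.3-fold (9.32 to 140.0), and AT1G63630 (99 and 1 reads, 108-fold, 18.9 to 4293) and AT3G23690 (50 and 6, 9.06-fold, 3.88 to 25.9) completed those named by fold. The auxin list stood at -1.95 (-2.12 without the pseudocount), percentile 0.03, and the NLR list at -0.87 (-1.12 at the bound), percentile 0.04. No SMXL gene and none of the 31 measured miRNA targets was called in this comparison, where 0 and 5 of them held the 50 reads that a call needs.

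The 11 higher loci included the chloroplast 16S rRNA genes ATCG01210 (7353 and 36892 reads, 4.62-fold, 4.501 to 4.73) and ATCG00920 (7343 and 36252, 4.54-fold, 4.43 to 4.66), near-identical copies whose reads cannot be assigned to one of them. XYP2 (AT2G13820, 0 and 68 reads, at least 20.9-fold), AT1G63750 (2 and 120, 55.2-fold, 15.0 to 461), TIM (2 and 102, 46.9-fold, 12.7 to 393), the meiosis gene SWI1 (AT5G51330, 13 and 72, 5.10-fold, 2.80 to 10.03) and AT2G07751 (21 and 108, 4.73-fold, 2.95 to 7.95) were the protein-coding loci of largest fold. The implied length of XYP2 was 2143 in the first set and 1038 in the second, while that of TIM was 2479 in both. TIM overlaps the transcribed pseudogene AT2G21172, whose reads could not be told apart from its own.

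The last comparison asked which reads differed with EIN5 and SKI2 mutated where RDR6 was mutated too, by setting the triple mutant against rdr6-11, within 1 set. EBF1 held 0 reads in rdr6-11 and 213 in the triple mutant, at least 71.1-fold higher. PHO2 held 38 and 544 (14.3-fold, 10.3 to 20.5), the aspartate kinase AK3 (AT3G02020) 16 and 425 (26.6-fold, 16.2 to 47.0) and the glucosyltransferase UGT75B1 (AT1G05560) 24 and 419 (17.5-fold, 11.6 to 27.6). AT2G18560 (0 and 137 reads, at least 45.7-fold) and PARVUS (AT1G19300, 0 and 71, at least 23.7-fold), a glycosyltransferase of xylan synthesis, were among the largest folds.

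By the rule of size 118 loci were higher and 3 lower, and 113 of the higher loci were protein-coding. The split was 107 against 6 with median of ratios, 103 against 7 with TMM, 98 against 13 with the reduced total and 158 against 3 when scaled to reads at miRNA genes. Others named by fold or change in reads were the B-box protein gene BBX16 (AT1G73870, 1 and 132 reads, 132-fold, 23.3 to 5259), the ethylene-response-factor gene RAP2.4 (AT1G78080, 1 and 102, 102-fold, 17.9 to 4073), GATA26 (AT4G17570, 1 and 101, 101-fold, 17.7 to 4033), GT18 (AT5G62220, 0 and 57, at least 19.0-fold), AT1G13360 (5 and 352, 70.5-fold, 29.9 to 218), AT4G32020 (6 and 340, 56.7-fold, 25.8 to 156) and AT5G54940 (2 and 113, 56.6-fold, 15.3 to 473). AT1G06000 and AT1G12020 each held 1 read in rdr6-11 and 72 and 66 in the triple mutant. AT1G18000 (31 and 544 reads) and AT1G18010 (23 and 502) are near-identical neighbours whose reads cannot be separated. TAS2 (5.89-fold, 3.87 to 9.31) and TAS3A (4.69-fold, 2.94 to 7.80) were higher in the triple mutant, though both stayed below 200 reads and TAS3A fell short of 4-fold under 3 of the 4 other scalings.

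The 3 lower loci were AT3G44570 (457 and 0 reads, at least 152-fold), its neighbour AT3G44580 (347 and 1, 347-fold, 61.8 to 13728), whose sequence in the triple mutant line was not examined here, and the PPR gene AT1G06580 (112 and 16, 6.99-fold, 4.12 to 12.7). The 31 measured miRNA targets had 2 higher members, PHO2 and the HD-ZIP III gene REV (AT5G60690, 4 and 51 reads, 12.8-fold, 4.69 to 48.6), and a median log2 fold of 1.59 (1.00 at the bound) at percentile 99.97. In the photosynthesis list RBCS1A (AT1G67090, 4.70-fold, 2.98 to 7.73) and PSAD1 (AT4G02770, 7.30-fold, 4.75 to 11.7) were higher among 26 measured members, RBCS1A short of 4-fold under the same 3 scalings, with a list median of 1.16 (1.17 at the bound) at percentile 99.9. Among loci with at least 50 reads in either library, 113 of 335 protein-coding genes were higher. Only 0 of 85 miRNA genes and 1 of 125 pseudogenes were. The ranks of the miRNA targets and the photosynthesis list were not separated from that difference, and the housekeeping median was higher still. The PPR list stood at 0.00, percentile 42.3, and turned negative with 3 of the other scalings (-0.19, -0.26 and -0.40), and over the 15 members with at least 50 reads in any library it was -0.84 at percentile 0.035. No SMXL, nitrogen assimilation, NLR or auxin receptor gene was called, but only 0, 2, 1 and 1 of them held the 50 reads that a call needs. The SMXL median was 1.79 (1.35 at the bound), with SMAX1 at 5 and 23 reads (4.61-fold, 1.71 to 15.5).

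The gains with and without RDR6 overlapped. Of 497 loci with enough reads in both comparisons 87 were higher in the double mutant than in Col-0 and 75 higher in the triple mutant than in rdr6-11. Both held for 70, against 13.1 for independent lists, and these 2 comparisons share no library. Among protein-coding genes 69 met both against 32.6. The losses gave no such overlap. Of the 59 loci lower in the double mutant than in Col-0, 54 had enough reads in both comparisons. Of the 59, 0 were among the 3 loci lower in the triple mutant than in rdr6-11. Independent lists would share 0.326, so the rule left little room for an overlap. In the triple over the double mutant 21 of the 59 were higher, against 3.32 for independent lists, but those comparisons share the double mutant library. Of the 98 gained loci without the loss in the triple mutant 75 had enough reads there and 63 were higher, among them EBF1 and PHO2. Of the 77 with that loss only 12 had enough reads, and 7 were higher. The difference between these groups follows in part from the criterion itself, which selects on the triple mutant. With a pseudocount of 1 read, the median fold of the 77 loci was 49.9 in the double mutant over Col-0 and 3.50 in the triple mutant over rdr6-11. That of the other 98 was 18.1 and 9.29. Where a locus held 0 reads in Col-0 or rdr6-11, as FMO and CRF2 did, the pseudocount sets its fold.

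**Figure D3:**
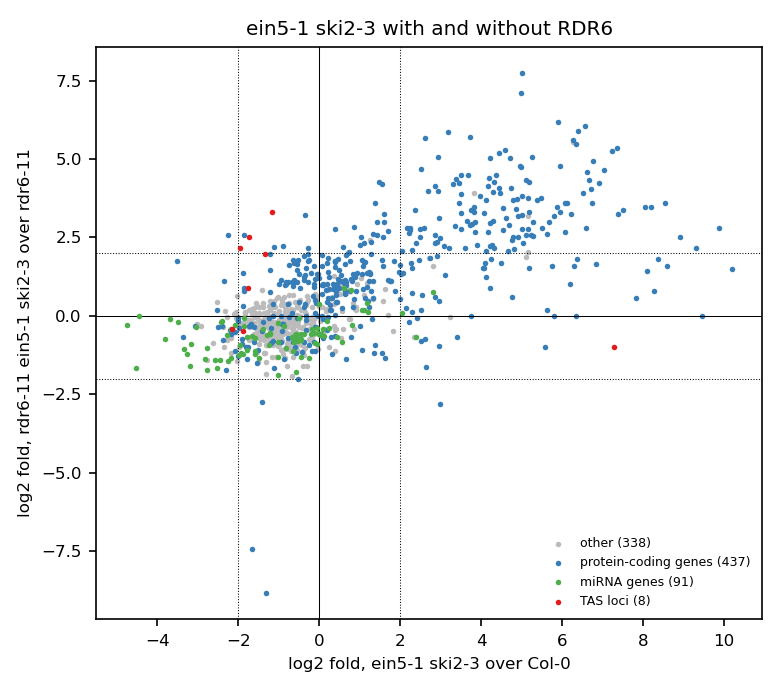
The same 874 loci, with the log2 fold of ein5-1 ski2-3 over Col-0 on the x axis and that of rdr6-11 ein5-1 ski2-3 over rdr6-11 on the y axis (pseudocount 1 read, dotted lines at 4-fold). Of 437 protein-coding genes 285 lie above 0 on both axes, and of 91 miRNA genes 70 lie below 0 on both.

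**Figure D4:**
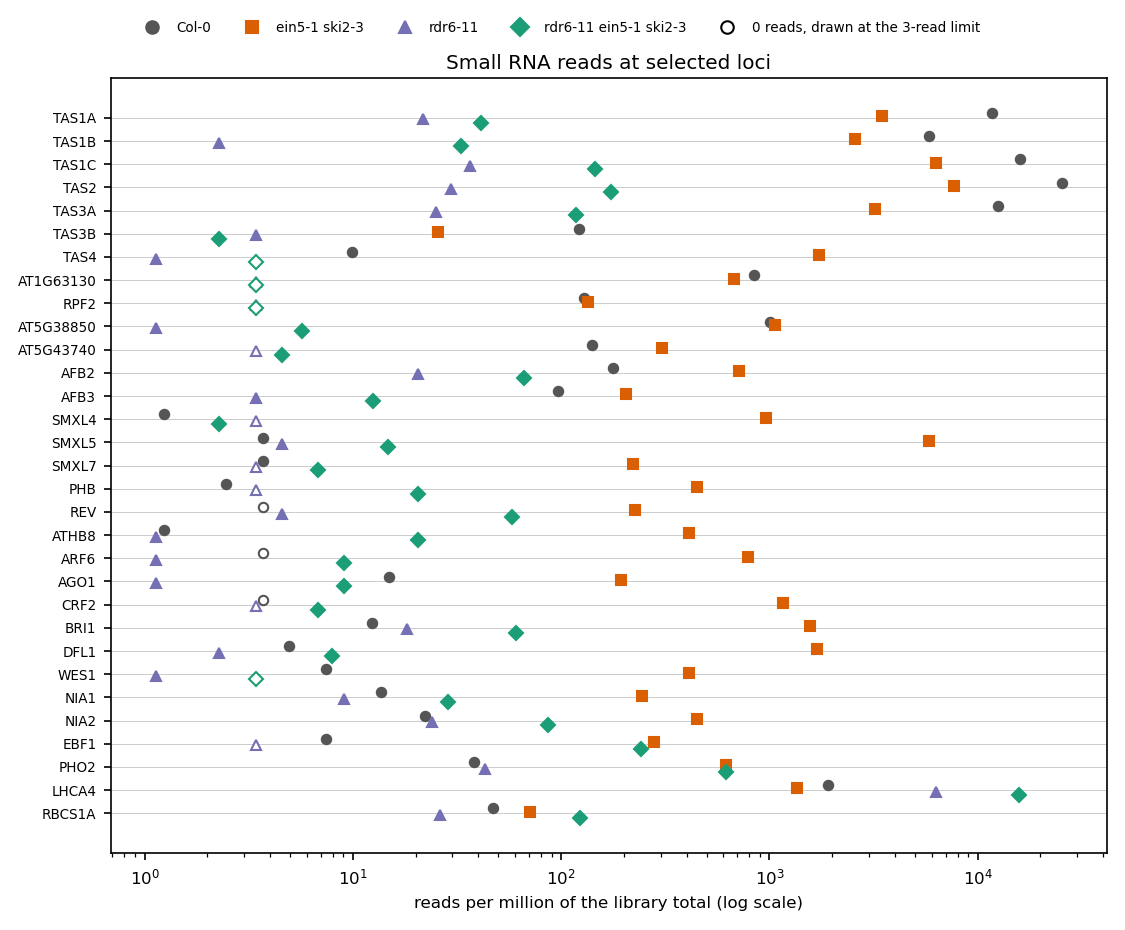
Reads scaled to the library total (RPM, log scale) at TAS loci and selected genes in the 4 libraries, 1 library each; open symbols are libraries with 0 reads, drawn at the limit of 3 reads, with the diamond covering the triangle where both rdr6-11 lines hold 0. SMXL5, with 3617 reads in ein5-1 ski2-3, and EBF1, with 213 reads in rdr6-11 ein5-1 ski2-3 and 0 in rdr6-11, show the gains with and without a loss in the triple mutant.

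The remaining lists held few reads. Of 12 housekeeping genes 10 were measured and none was called in any of the 4 comparisons, though their median log2 fold was 1.22 in the double mutant over Col-0, 1.11 in the triple over the double mutant, 0.96 in rdr6-11 over Col-0 and 1.37 in the triple mutant over rdr6-11 (1.27, 1.17, 1.13 and 1.40 at the bound). Among them AT1G07920, AT1G07930, AT1G07940 and AT5G60390 held similar counts (82, 90, 91 and 73 in the triple mutant). Reads shared between these genes may enter the median more than once, which was not tested. Of the 11 clock genes PRR7 was measured, of the 6 flower genes PI, and of the 7 root genes SHR and SCR, none with 50 reads in any library and so none called. In the double mutant over Col-0 their reads were 8 and 2 for PRR7 (5.202-fold, 1.038 to 50.3), 10 and 1 for PI (13.0-fold, 1.85 to 564), 9 and 1 for SHR (11.7-fold, 1.62 to 513) and 28 and 4 for SCR (9.10-fold, 3.19 to 35.7). SCR was also higher in the triple mutant than in rdr6-11 (20 and 3 reads, 6.68-fold, 1.98 to 35.1). In the list of decay and silencing genes AGO1 was higher in the double mutant and 21.4-fold lower (10.5 to 50.6) in the triple than in the double mutant, and the other 2 measured members were not called.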

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

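All tests in this part were chosen after the results were seen. The loci given here moved in opposite directions when EIN5 and SKI2 were mutated with RDR6 (double mutant over Col-0) and without it (triple mutant over rdr6-11), each beyond its counting interval, though for TAS1A in the triple mutant over rdr6-11 (1.90-fold, 1.06 to 3.50) the lower bound fell below 1 under 3 of the 4 other scalings. With 1 library per genotype the difference between the effects was not tested. On the log2 scale, with a pseudocount of 1 read, TAS1B had -1.17 with RDR6 and 3.32 without, TAS1A -1.75 and 0.89, TAS1C -1.34 and 1.97, TAS2 -1.73 and 2.51, and TAS3A -1.95 and 2.18. Summed over the 8 TAS loci the ratio was 0.35 with RDR6 and 4.104 without. AT3G22210 had -1.85 and 0.89, LHCA4 -0.50 and 1.33, CP12-2 -1.88 and 1.38, and DIN10 -3.53 and 1.75.

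The TAS reads of the triple mutant, 455 against 111 in rdr6-11, were weighed first. Library scaling is argued against, since the lowest of the 4 other scalings left a 3.12-fold difference with a lower bound of 2.53. Reads carried over from the double mutant library would need 2.22% of its TAS reads. The share was checked at the 76 loci outside TAS that were higher in the double mutant than in both Col-0 and the triple mutant. Of these, 8 held fewer triple mutant reads than the lower counting limit of that share allows, SMXL5 with 13 where 80.2 would be needed. Carry-over from the Col-0 library, which would need 0.596%, stays open: of 15 loci 1 fell below, AT1G63130 with 0 reads where 4.07 would be needed, so the counts could not decide. A biological difference between the genotypes also stays open and was not tested.

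The second pattern is the larger chloroplast share in rdr6-11 and the triple mutant. The room left by lost TAS reads is argued against, since it would give 1.08-fold at most and chloroplast reads were 2.22-fold higher in rdr6-11 than in Col-0 (2.201 to 2.24). Different locus models in the 2 sets are argued against too, since 0 of 131 chloroplast loci with reads in both libraries differed in implied length. A difference in library making or handling between the sets may be the cause and cannot be told apart from RDR6, because the sets, recognised by lengths that differed at 3.6% of loci, follow the RDR6 genotype. In the triple over the double mutant the chloroplast share differed 2.77-fold (2.74 to 2.79), and an effect of RDR6 itself stays among the open explanations.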

How the results depend on the processing

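The 4 settings added after the data were seen are the authors' library totals, equal lengths, no overlap with small RNA genes, and totals without organelles. Over 9 counts of loci and 17 settings, 101 of 153 alternative counts were within 1.5 times the main one, among them all from those 4 settings, and 52 were not. The cause of a move was not tested except where the setting itself adds or removes loci. With a minimum of 20 reads the double mutant over Col-0 had 429 higher and 100 lower loci, the triple over the double mutant 215 and 193, the triple mutant over rdr6-11 380 and 25, rdr6-11 over Col-0 32 higher, and 130 met both criteria. With a minimum of 100 reads there were 86 higher in the double mutant, 57 higher and 68 lower in the triple against it, 7 higher in rdr6-11, 45 higher in the triple over rdr6-11, and 48 by both criteria. Without a minimum the counts were 3103 and 381, 794 and 2991, 622 and 982, 3431 and 496, and 874 by both, in the order double over Col-0, triple over double, rdr6-11 over Col-0, triple over rdr6-11, higher before lower. At 2-fold 215 loci were lower in the double mutant, 264 higher and 159 lower in the triple against it, 65 higher and 34 lower in rdr6-11, 219 higher and 69 lower in the triple over rdr6-11, and 129 met both. At 8-fold there were 15 lower in the double mutant, 27 higher in the triple against it, 3 higher in rdr6-11, 70 higher in the triple over rdr6-11, and 42 by both. Requiring the counting interval to reach 4-fold left 27, 37, 6 and 77 for lower in the double mutant, higher in the triple against it, higher in rdr6-11, and higher in the triple over rdr6-11. A pseudocount of 5 left 7 higher in rdr6-11. Among protein-coding loci alone 14 were lower in the double mutant, 59 higher in the triple against it, and 7 higher and 14 lower in rdr6-11; leaving out TAS and miRNA loci gave 34 lower in the double mutant. For loci lower in the double mutant TMM gave 95 and the reduced total 134, and for loci lower in the triple mutant than in rdr6-11 median of ratios gave 6, TMM 7 and the reduced total 13. Scaling to miRNA reads gave 223 higher in the triple than in the double mutant, and the summed protein-coding fold of that comparison turned from 0.883 to 1.52. Of 546 alternative folds of named loci 480 stayed within the counting interval, 66 did not and 0 changed sign. Of 208 alternative list medians 172 moved by less than 0.5 and 36 by more, and those that changed sign were the PPR list in the triple mutant over rdr6-11 (4 settings), the nitrogen list in the triple over the double mutant and the photosynthesis list in the double mutant over Col-0 (-0.09 with the reduced total). All 24 class shares moved with the reduced denominator. The planned split by size class or strand was not run, since the table has no such columns. No paired analysis was possible within a comparison, because each sets 1 library against 1; a fit of the EIN5 and SKI2 effect over both sets, with 1 residual degree of freedom, was not made. Depth limits calls to loci with 50 reads, 413 to 614 per library.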

Other observations

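The groups, families and tests in this part were chosen after the data were seen. Some further genes, picked by hand from the called loci, are given as values only. The receptor kinases PXY (AT5G61480) and BAM3 (AT4G20270) of vascular development held 5 and 3 reads in Col-0 and 229 and 165 in the double mutant, and were 46.2-fold (22.1 to 116) and 29.1-fold (14.4 to 68.6) lower in the triple than in the double mutant. GTR2 (AT5G62680), a glucosinolate transporter, held 0 reads in Col-0 and 56 in the double mutant (at least 24.3-fold higher). All 5 HD-ZIP III genes were higher in the double mutant, with REV, PHV (AT1G30490) and ATHB15 (AT1G52150) at 0 reads in Col-0 and at 140, 63 and 73 in the double mutant, and all were lower in the triple than in the double mutant, REV by 3.88-fold (2.79 to 5.45), just short of the rule of size. The epimerases GAE6 and GAE1 (AT4G30440) were higher in the double mutant (71.7-fold and 27.8-fold) and in the triple mutant over rdr6-11 (12.7-fold and 7.69-fold).

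Of the 31 measured miRNA targets 15 held 50 reads in Col-0 or the double mutant. The 3 HAM genes, targets of miR171, were not called, with 98 and 92, 108 and 89, and 113 and 113 reads in Col-0 and the double mutant.

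One hypothesis was that fewer trigger miRNAs could account for the lower TAS reads in the double mutant. miR173, the trigger at TAS1 and TAS2, was 7.10-fold lower (6.17 to 8.20), and those 4 loci were 2.94-fold lower in sum (2.88 to 3.00), so for them it stays open. For the TAS3 loci it is argued against: they were 3.88-fold lower (3.70 to 4.07) while miR390, their trigger, was 2.12-fold higher (2.01 to 2.24).

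The third pattern is the number of miRNA families lower in the double mutant. Of 49 families with at least 50 reads in any library 15 were at least 4 times lower, led by miR169 (2502 and 159 reads, 12.1-fold, 10.3 to 14.3), while miR408 was 4.24-fold higher (2.63 to 7.09) and miR398 2.52-fold higher (2.34 to 2.72). Library scaling stays open, because the count depends on the reference. The 4 other scalings, which all shift this fold down, gave 16 to 24 families. Reads at miRNA families gave 16, and the median family, itself 2.65-fold lower, gave 2. The miRNA reads are mostly those of miR159 and miR396, with 174311 and 115576 of 333477 in the double mutant. These families were 1.13-fold and 1.31-fold higher there than in Col-0, so a miRNA-read reference follows them and not the typical family. A trait of this single library could not be excluded: of the 15 families 10 were, by the whole counting interval, lower in the triple mutant over rdr6-11 than all families together (0.685), as were 13 of the 34 others (11 and 22 by the fold alone), and miR169 was at 0.763 and miR172 at 0.881 there, or above 1 when scaled to miRNA reads (1.11 and 1.29). Scaled to the library total, 44 of the 49 families were below 1 in the triple mutant over rdr6-11, with a median of 0.614. Of the 15 families 0 were above 1 there. The Spearman rho of the family folds between that comparison and the double mutant over Col-0 was 0.51. An effect of the ein5-1 ski2-3 genotype stays open and was not tested apart from the library.

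AT3G44570 and AT3G44580, neighbouring genes, held 458 and 400 reads in Col-0, 140 and 97 in the double mutant, 457 and 347 in rdr6-11, and 0 and 1 in the triple mutant. Whether the triple mutant line carries a changed or missing sequence at these genes was not examined here. Near-identical locus pairs had near-identical counts, for example 46227 and 44801 reads in Col-0 at the rRNA loci AT3G41768 and AT2G01010.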
